A study of Mus musculus with 13 samples.

How the data were processed

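RNA of mouse mammary organoids was measured on 1-colour Agilent 4x44K arrays after low-input amplification and Cy3 labelling, per the labels' protocols. Of 14 arrays, 12 were hybridised in batch 2, with each of the 4 groups complete, and 2 in batch 1, which repeated the normal Matrigel samples of mice A and B. The comparisons use the 12 arrays of batch 2. Mice are separate animals, so the spread between arrays of a group includes that between animals. Slides hold up to 3 arrays here, and slides 3, 4, 6 and 8 hold more than 1 group.

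The deposited intensity of each spot is Agilent's processed signal, which had spatial detrending and replacement of low values by surrogates, per the file headers. The headers name Feature Extraction version 9.5, while the submitters' processing notes name 9.1; the headers were followed. The authors' deposited log2 values, 1 column per sample, were also used. Each column followed its array's log2 processed signal at r of 0.999 or more with a median of 5.91 to 5.98; the centring is not given in the sources used here. The column for normal Matrigel B averages both batches. From the intensities, log2 values minus each array's 75th percentile were taken, outlier-flagged spots (52 to 139 per array) and control spots left out, and the spots of a probe averaged, which gave 41174 probes. A probe was kept if well above background on every array of at least 1 group with at least 2 values in every group, as 26604 were. Each gene was represented by its probe with the highest mean; for 6026 genes with several probes, probes passed in opposite directions for 87 genes between the gels in tumor organoids and 256 between the tissues in Matrigel. Names came from the RefSeq names of GRCm38.p6 for 22951 probes (55.7%) and otherwise from the files; no coordinates are given. On all 12 arrays, 14905 genes were well above background.

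limma 3.58.1 (R 4.3.3, version 1.17.8 of data.table) was fitted with a term per group (residual df 8, prior df 2.75), and p-values were adjusted by Benjamini-Hochberg in each comparison, with a threshold of 0.05. A gene called higher or lower passed it. A gene not well above background on any array of 1 group has only a bound there: "at least N-fold" sets the bright group's mean against the mean of, per array, the higher of the lowest signal among probes well above background and the gene's own. A comparison of 3 arrays with 3 allows no exact permutation p under 0.10.

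Before the data were examined, 24 gene lists with 495 members were fixed, 469 of them tested. They are markers of luminal, hormone-sensing, basal, fibroblast, endothelial, leukocyte and adipocyte cells and EMT, and genes of milk, basement membrane, interstitial ECM, proteases, integrins, junctions, cell cycle, hypoxia, interferon, inflammation, SRF/YAP/TGF-beta, cholesterol, FGF/ERK, Wnt, keratinization and stress. They were tested with camera (preset correlation 0.01) over 18239 genes, adjusted over 144 tests. Of 50 calls none passed with an estimated correlation (17 at an unadjusted p under 0.05), and 29 passed by fry, which called 37 of the 144. The genes named were also chosen by a rule fixed then: the 10 per direction with the largest change and no overlap, up to 5 one-sided genes per direction, up to 4 passing members of each list or its 2 brightest, and 12 fixed genes. The rule gives 275 genes, of which 126 are named. Of the others 2 are not reported here, and the rest were left out for length, several of them after their dependence on single arrays or scalings was seen.

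Letters pair the gels within a tissue. Deviations of same-mouse arrays from their group means correlated across genes at 0.24 and -0.243 for normal mice A and B and -0.0583, 0.323 and 0.419 for tumor mice A, B and C. The alternatives were quantile normalization, normexp (offset 50), the authors' values, 2 other filters on dim probes, flagged spots kept, 2 other rules for several probes, 3 uses of batch 1, mouse, letter and slide blocks, only the groups compared, trend and robust variances, array weights, a 2-fold threshold and leaving out each array. On simulated data with 100 genes changed 4-fold among 18274, 76 were recovered for the gel effect in normal and 72 in tumor organoids, 74 between tissues in Matrigel, 69 in collagen I, 41 for the difference of effects and 88 for the averaged effect. For 100 changed 2-fold these were 30, 25, 27, 35, 2 and 63. Figures were drawn with matplotlib 3.10.9.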

Results

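Mammary epithelial organoids, multicellular fragments freed from tissue with collagenase and trypsin, were prepared from the glands of normal FVB mice or from PyMT mammary tumors. PyMT mice develop mammary carcinomas driven by the polyoma virus middle T antigen. The organoids were embedded in Matrigel, a laminin-rich basement membrane gel, or in rat-tail collagen I at 3 mg/ml, the main fibrillar collagen of connective tissue. They were grown for 4 days with 2.5 nM FGF2, a growth factor, and their RNA was read on 1-colour Cy3 arrays. The 12 arrays compared fall into 4 groups of 3 mice: normal organoids in Matrigel (mice A, B and D) or collagen I (A, B and C), and tumor organoids in either gel (A, B and C). A shared letter within a tissue marks the same mouse, and normal and tumor mice are different animals. Of the genes on the array, 18274 were tested, 15056 of them with a gene symbol. Fold changes are given on the log2 scale with the standard error of the limma fit after ±.

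The arrays were not equally bright. The 75th percentile of the processed signal was 956 ± 247 (SD, n = 3) for normal organoids in Matrigel and 1076 ± 126 in collagen I. For tumor organoids it was 463 ± 96.3 in Matrigel and 738 ± 65.4 in collagen I. Spots well above background made up 66.2 ± 2.81% and 67.6 ± 3.58% of the normal arrays in Matrigel and collagen I, and 57.4 ± 1.11% and 65.0 ± 3.68% of the tumor arrays. Probes for spike-in control RNA stood 2.55 ± 0.21 log2 units over the 75th percentile on the tumor Matrigel arrays. They stood 0.65 ± 0.36, 0.34 ± 0.17 and 0.84 ± 0.26 above it in normal Matrigel, normal collagen I and tumor collagen I. Across genes, arrays of 1 group correlated at r = 0.989 to 0.992 in normal collagen I, 0.965 to 0.983 in normal Matrigel, 0.962 to 0.972 in tumor collagen I and 0.975 to 0.985 in tumor Matrigel. Genes are not independent replicates, so these are descriptions. On the second principal component (14.9% of the variance) normal Matrigel A was at 54.7 against 18.2 and 24.8 for its group, tumor Matrigel C at -1.11 against 43.9 and 35.2, and tumor collagen I at -91.6 to -20.3.

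**Figure D1:**
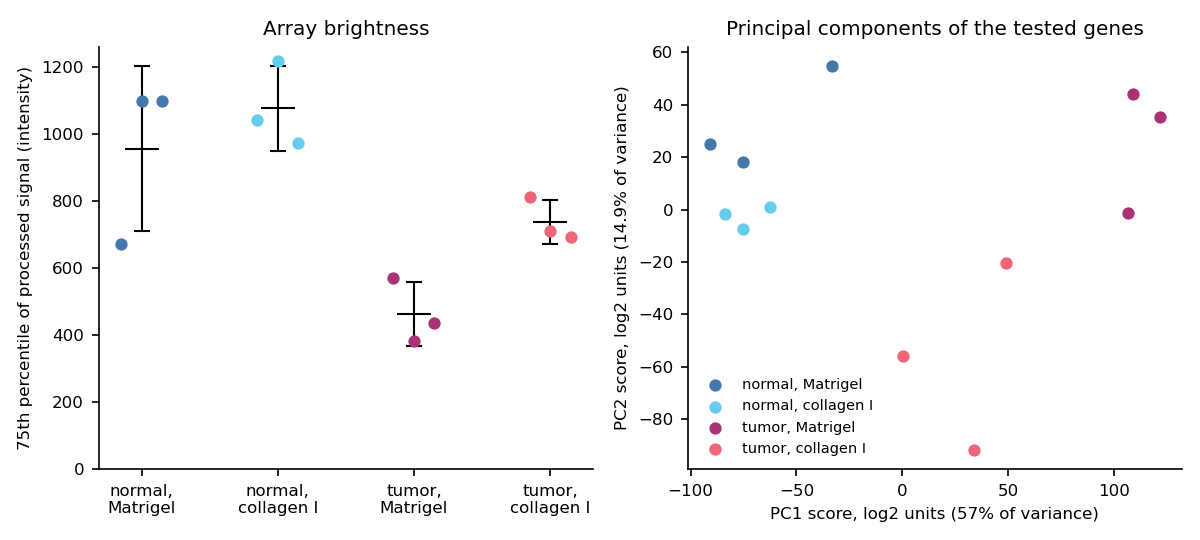
Left, 75th percentile of the processed signal (intensity) of each of the 12 arrays, as points, with the group mean and SD; the tumor Matrigel arrays lie lowest, from 383 to 570. Right, scores of these arrays on the first 2 principal components (log2 units) of the tested genes, by group. The first (57% of variance) runs from normal over tumor collagen I to dim tumor Matrigel.

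The effect of the gel in normal organoids came down to few single genes. Compared with Matrigel, 7 genes were higher and 1 was lower in collagen I. Foxj1, a transcription factor of motile cilia, rose by 3.28 ± 0.35 (limma with Benjamini-Hochberg adjustment, adjusted p = 0.00798). Irg1, which encodes the itaconate-forming enzyme of activated macrophages, rose by 2.70 ± 0.33, Mme, the cell-surface peptidase neprilysin, by 1.90 ± 0.21, and Nr4a2, an orphan nuclear receptor, by 1.84 ± 0.23 (limma adjusted p = 0.0172, 0.0105 and 0.0177). The transcript 3300001A09Rik rose by 3.51 ± 0.43 (limma adjusted p = 0.0172). The transcripts 2310002L13Rik and 1500041J02Rik were not well above background in Matrigel and were at least 6.07-fold and 3.51-fold higher in collagen I (limma adjusted p = 0.0065 and 0.00493). The reverse held for 5830431A10Rik, at least 2.14-fold lower in collagen I (limma adjusted p = 0.00798).

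None of the 12 genes of epithelial identity, mesenchymal transition and matrix contact named in every comparison passed in normal organoids by limma. Their adjusted p ran from 0.25 for Mmp14, a membrane-bound collagenase, at 0.83 ± 0.22, to 0.986. The adhesion molecule Cdh1 (E-cadherin) was at -0.29 ± 0.46, the keratins Krt8 and Krt14 at -0.14 ± 0.23 and 0.15 ± 0.75, and vimentin (Vim) at -0.27 ± 0.55. The transition factors Snai1, Snai2, Twist1 and Zeb1 were at -0.07 ± 0.37, -0.52 ± 0.30, 0.16 ± 0.85 and -0.32 ± 0.42. The collagen receptor subunit Itga2 was at 0.08 ± 0.30, smooth muscle actin (Acta2) at 0.07 ± 0.17 and the basal factor Trp63 at -0.18 ± 0.32. Acta2 has probes that disagree, and their mean passed between the gels in tumor organoids and between the tissues in both gels.

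In normal organoids 12 gene lists passed by camera with its preset correlation, but not with an estimated one. No member of the 24 lists passed over all genes tested by limma, and 78 of 451 had an unadjusted p under 0.05. Values are thus given in place of calls. The leukocyte markers, fixed to trace immune cells carried along with the epithelium, had 9 of 15 members higher when adjusted over the list alone. Their median was 1.49 (camera adjusted p = 7.07e-08; adjusted p = 0.365 with an estimated correlation). The macrophage genes Lyz2 and Cd68 were at 2.28 ± 0.82 and 1.16 ± 0.43. Beside them, the inflammatory and acute-phase genes had 6 of 25 higher over the list alone and a median of 0.76, or 0.57 with genes dim on 1 side at their bound (camera adjusted p = 9.6e-08; adjusted p = 0.0947 with an estimated correlation). The acute-phase protein haptoglobin (Hp) was at 1.60 ± 0.39. The matrix proteases and their inhibitors (protease genes) had 3 of 31 higher over the list alone and a median of 0.66 (camera adjusted p = 5.53e-05; adjusted p = 0.411 with an estimated correlation). The inhibitor Timp2 was at 0.66 ± 0.24. The SRF, YAP and TGF-beta target genes had 4 of 24 higher over the list alone and a median of 0.26 (camera adjusted p = 0.000112; adjusted p = 0.396 with an estimated correlation). The integrins and matrix receptors had 0 of 23 called over the list alone, 3 higher at an unadjusted p under 0.05, and a median of 0.27 (camera adjusted p = 0.011; adjusted p = 0.383 with an estimated correlation). The hormone-sensing luminal markers had 1 of 11 higher over the list alone and a median of 0.52 (camera adjusted p = 0.0459; adjusted p = 0.635 with an estimated correlation). Cd44, a hyaluronan receptor and Wnt target, was at 0.64 ± 0.23.

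By camera p the cholesterol biosynthesis genes led the lists lower in collagen I. Of 22 members 1 was lower over the list alone and the median was -0.53 (camera adjusted p = 3.88e-09; adjusted p = 0.568 with an estimated correlation). No member of the lists that follow passed by limma over its list alone, so the count at an unadjusted p under 0.05 is given. The cell cycle genes had 1 of 28 lower at that level and a median of -0.56 (camera adjusted p = 6.64e-07; adjusted p = 0.681 with an estimated correlation). The replication genes Mcm6 and Pcna were at -0.57 ± 0.38 and -0.38 ± 0.24. The hypoxia and glycolysis genes had 6 of 19 lower and a median of -0.64 (camera adjusted p = 5.98e-06; adjusted p = 0.681 with an estimated correlation). Without normal Matrigel A the list lost its call, at -0.13 (camera adjusted p = 0.268): that array stood over Matrigel B and D by medians of 1.13 and 1.94 for this list, while over B it was at -0.19 in batch 1. The glycolytic enzymes Aldoa and Ldha were at -0.56 ± 0.24 and -0.64 ± 0.28. The interferon-stimulated genes had 2 of 23 lower and a median of -0.39 (camera adjusted p = 0.00103; adjusted p = 0.778 with an estimated correlation). The milk protein and secretory genes had 1 of 15 lower and a median of -0.53 (camera adjusted p = 0.0111; adjusted p = 0.681 with an estimated correlation). The adipocyte markers had 1 of 6 lower and a median of -0.56 (camera adjusted p = 0.0295; adjusted p = 0.681 with an estimated correlation).

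Slides 3 and 4 each hold a Matrigel and a collagen I array of different normal mice. With slide as a block, fixed here and below (residual df 2), 0 genes passed by limma and 1874 had an unadjusted p under 0.05. A random block kept all 8 calls. The differences within slides 4 and 3 correlated with those of the other arrays at r = 0.189 and 0.564. The leukocyte markers had a median of 1.57 with slide as a block, 0.51 within slide 4 and 2.70 within slide 3, and the inflammatory and acute-phase genes 0.70, 0.66 and 0.69. For the protease genes these were 0.33, 0.15 and 0.79, for the SRF, YAP and TGF-beta target genes 0.26, 0.53 and 0.25, and for the hormone-sensing luminal markers 0.87, 1.16 and 0.41. For the cholesterol biosynthesis genes they were -0.38, -0.15 and -0.49. The remaining lists lost their call with slide as a block: integrins and matrix receptors at 0.17, 0.06 and 0.37 (camera adjusted p = 0.218), cell cycle genes at -0.23, 0.10 and -0.75 (0.0757) and hypoxia and glycolysis genes at -0.21, 0.38 and -0.59 (0.178). The interferon-stimulated genes lost it at 0.05, 0.58 and -0.38 (camera adjusted p = 0.465), the milk protein and secretory genes at -0.63, -0.42 and -0.77 (0.0736) and the adipocyte markers at -1.14, -2.81 and 0.19 (0.0618). The mouse as a random block ended the calls of the hormone-sensing luminal markers (camera adjusted p = 0.0723) and the adipocyte markers (0.0511). Without Matrigel D these lists were at 0.20 and -0.17 without a call (camera adjusted p = 0.427 and 0.579), as without collagen I A (0.0676 and 0.156), and the first also without collagen I C or any tumor Matrigel array (0.0542 to 0.116). The interferon-stimulated genes lost theirs without Matrigel A, at -0.17, or collagen I B, at -0.12 (camera adjusted p = 0.204 and 0.118). Medians that moved over 1.5 times with the call kept were 0.90 for the leukocyte markers and 0.40 for the protease genes without Matrigel B, -0.34 for the cell cycle genes without A and 0.14 for the integrins and matrix receptors without collagen I C. So were -0.97 for the hypoxia and glycolysis genes without Matrigel D, -0.70 and -0.65 for the interferon-stimulated genes without Matrigel D and collagen I A, and -0.92 and -0.91 for the adipocyte markers without Matrigel A and B.

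The count of 8 genes in normal organoids, with 1658 at an unadjusted p under 0.05, was 71 with the mouse as a random block and 0 with it as a fixed block (limma; 1659 at an unadjusted p under 0.05). Weights by array quality, with the lowest weight of 0.424 on the Matrigel array of mouse A, gave 1686. Other scalings gave 18, 72.2% of them higher, with quantile normalization, 4 with 100% higher with normexp background correction, and 88 with 69.3% higher with both; the main split was 87.5% higher, and the authors' values gave 75% higher of 8. Left out in turn, Matrigel arrays A, B and D gave 15, 4 and 18 genes, collagen I array B gave 4, tumor Matrigel C 23 and tumor collagen I B 13. The transcript 3300001A09Rik lost its call without Matrigel B or any collagen I array (limma adjusted p = 0.0508 to 0.123). Irg1 and Mme lost it without Matrigel B or collagen I A or B (0.061 to 0.106), and Nr4a2 without any Matrigel array or collagen I B or C (0.0507 to 0.136). The other 4 kept it with any 1 array left out. Normexp ended the calls of Irg1, Mme, 2310002L13Rik, 1500041J02Rik and 5830431A10Rik (limma adjusted p = 0.181 to 0.997), with quantile normalization those of all of these but Mme (0.0558 to 0.289), and the authors' values those of Irg1 and 1500041J02Rik (0.0603 and 0.0721).

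Many more genes passed between the gels in tumor organoids. Of 18274 genes, 2883 were higher and 2206 lower in collagen I than in Matrigel, 27.8% of those tested. Periostin (Postn), a matricellular protein, rose by 3.89 ± 0.55, and Pappa, a protease of insulin-like growth factor binding proteins, by 3.69 ± 0.45 (limma adjusted p = 0.00191 and 0.00128). Gpr177, the carrier that Wnt ligands need for secretion, rose by 4.12 ± 0.46 (limma adjusted p = 0.000984). Ddit3 (CHOP), a transcription factor of the integrated stress response, was at -3.23 ± 0.26 and Csf3, the granulocyte colony-stimulating factor, at -3.21 ± 0.23 (limma adjusted p = 0.000231 and 0.000213). Also lower were Jsrp1 at -4.37 ± 0.86, the cytokine Il19 at -4.07 ± 0.86 and the secretory-cell factor Bhlha15 at -3.50 ± 0.61 (limma adjusted p = 0.0061, 0.00771 and 0.00362). Fcer2a, a low-affinity IgE receptor, was not well above background in collagen I and was at least 16.3-fold lower there, 8.55-fold without tumor Matrigel B and 34.7-fold without C (limma adjusted p = 0.00306).

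The unfolded protein and integrated stress response genes (stress response genes) fell in collagen I against the dim Matrigel arrays: 15 of 20 were lower and 0 higher, 17 lower over the list alone, with 18 lower at an unadjusted p under 0.05. Their median was -1.22 (camera adjusted p = 3.88e-09; adjusted p = 0.0947 with an estimated correlation). After Ddit3 came its partner and target Trib3 at -2.59 ± 0.19, the glutathione-degrading enzyme Chac1 at -2.12 ± 0.31 and the factor Atf5 at -1.66 ± 0.26 (limma adjusted p = 0.000213, 0.00211 and 0.00256). The FGF and ERK feedback and target genes (FGF and ERK genes) fell too, 9 of 20 lower and 0 higher, the same numbers over the list alone, with a median of -0.71 (camera adjusted p = 0.00879; adjusted p = 0.568 with an estimated correlation). They include the ERK phosphatase Dusp6 at -1.48 ± 0.30 and the receptor tyrosine kinase antagonist Spry2 at -1.33 ± 0.19 (limma adjusted p = 0.00658 and 0.00188). Another probe of Spry2 was at -0.52. Of the hypoxia and glycolysis genes 6 of 19 were lower, 7 over the list alone, with a median of -0.99 (camera adjusted p = 0.000902; adjusted p = 0.778 with an estimated correlation). The vasoactive peptide gene Adm was at -2.58 ± 0.67 and Ndrg1, induced by low oxygen, at -1.83 ± 0.54 (limma adjusted p = 0.0178 and 0.0299). Of the basement membrane components 5 of 21 were lower, also over the list alone, with a median of -0.68 (camera adjusted p = 0.0212; adjusted p = 0.635 with an estimated correlation). They include Col18a1, the collagen XVIII chain, at -1.30 ± 0.28, and the laminin chain Lamb2 at -0.95 ± 0.17 (limma adjusted p = 0.00824 and 0.0044).

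The lists that follow had no camera call in tumor organoids, and their members passed in the same numbers over the list alone. The protease genes had 4 of 31 higher and 0 lower, with a median of 0.25, or 0.18 with dim genes at their bound (camera adjusted p = 0.438): Mmp13, a collagenase, rose by 3.06 ± 0.70, the aggrecanase Adamts5 by 2.67 ± 0.32 and the elastase Mmp12 by 2.58 ± 0.42 (limma adjusted p = 0.011, 0.00128 and 0.00296). The integrins and matrix receptors had 5 of 23 higher and 4 lower, with a median of -0.01 and a mean of 0.20 (camera adjusted p = 0.707). The collagen-binding subunit Itga11 rose by 2.04 ± 0.40 and Itgb6, which pairs with alpha v, by 1.67 ± 0.33, while the laminin-binding subunit Itga3 was at -1.47 ± 0.29 (limma adjusted p = 0.00594, 0.00648 and 0.00596). The luminal epithelial markers had 1 of 16 higher and 4 lower and a median of -0.50 (camera adjusted p = 0.0776). The epithelial factor Elf3 was at -1.40 ± 0.21 and Krt18 at -0.95 ± 0.19 (limma adjusted p = 0.00211 and 0.00596). The inflammatory and acute-phase genes had 3 of 25 higher and 4 lower and a median of 0.19 (camera adjusted p = 0.852). The chemokine Ccl5 was at -2.38 ± 0.40 (limma adjusted p = 0.00337). The leukocyte markers had 1 of 15 lower, Cd68 at -2.92 ± 0.43 (limma adjusted p = 0.00211), and a median of 0.09, or 0 with dim genes at their bound (camera adjusted p = 0.707). The keratinization genes had 1 of 18 higher, Krt10 at 1.45 ± 0.25, and 1 lower, Krt15 at -2.57 ± 0.58 (limma adjusted p = 0.00344 and 0.00996), with a median of 0.53 (camera adjusted p = 0.661). The cholesterol biosynthesis genes had 4 of 22 higher, with Idi1, isopentenyl diphosphate isomerase, at 1.47 ± 0.22 (limma adjusted p = 0.00236), and a median of 0.01 (camera adjusted p = 0.545). The interferon-stimulated genes had 1 of 23 higher, Ifit2 at 1.68 ± 0.35 (limma adjusted p = 0.00752), and a median of -0.06 (camera adjusted p = 0.862).

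Of the 12 genes named in every comparison, Snai1, a repressor of E-cadherin, was lower in collagen I at -1.53 ± 0.37 (limma adjusted p = 0.0128), and 0.0521 without tumor collagen I array A. Among the EMT transcription factors and mesenchymal markers (EMT genes) 2 of 14 were higher and 3 lower, with fibronectin (Fn1) up by 1.41 ± 0.31 (limma adjusted p = 0.00935), and the list's median was 0.54, or 0.07 with dim genes at their bound (camera adjusted p = 0.545). Krt8 was at -0.68 ± 0.23 (limma adjusted p = 0.0487), a call lost with the sign turned with quantile normalization, normexp and quantile normalization, and in the authors' values. Krt8 also lost it with 9 of the 12 arrays left out in turn (limma adjusted p = 0.0565 to 0.17); only without normal Matrigel A, tumor Matrigel A or tumor collagen I B was it kept, and with the mouse as a fixed block it was lost (0.0552). Cdh1 was at 0.19 ± 0.46, Krt14 at 0.64 ± 0.75, Vim at 0.14 ± 0.55, Snai2 at 0.55 ± 0.30, Twist1 at -0.27 ± 0.85 and Zeb1 at 0.95 ± 0.42, which passed with the mouse as a fixed block (limma adjusted p = 0.044). Mmp14 was at 0.39 ± 0.22, Itga2 at -0.12 ± 0.30, Acta2 at -0.15 ± 0.17 and Trp63 at 0.08 ± 0.32, all without a call (limma adjusted p = 0.114 to 0.874).

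Of the 5089 genes that passed in tumor organoids 757 were dim on 1 side. With normexp background correction the count was 1251, of which 39.2% were higher against 56.7% in the main values, and the median of all genes shifted to -0.33. Under normexp Pappa, Gpr177, Mmp12 and Ifit2 lost their call at 0.89, 0.81, 0.04 and 0.03, as did Ndrg1 and Krt8. Quantile normalization ended those of Ndrg1 and Krt18, and the authors' values these and that of Col18a1 (limma adjusted p = 0.0653). Pappa and Il19 were well above background on 2 of 3 arrays of the gel where they were low, and Gpr177, Jsrp1, Mmp12 and Zeb1 on 1. With dim arrays at their bound they were at 3.50, -3.73, 3.67, -3.62, 2.55 and 0.79. Camera lost the basement membrane components with quantile normalization (adjusted p = 0.123) and normexp (0.492), the hypoxia and glycolysis genes with both (0.0616 and 0.136), and the FGF and ERK feedback and target genes with normexp (0.0967). The basement membrane components also lost it without tumor Matrigel A or tumor collagen I A (camera adjusted p = 0.0542, and 0.0656 at -0.41), and the FGF and ERK genes were at -0.42 without tumor Matrigel A. Without tumor Matrigel B or tumor collagen I A the count was 2895 or 2744. Adm then lost its call (limma adjusted p = 0.0691 and 0.0696), as did Ndrg1, also without tumor Matrigel C (0.0589 to 0.114). Slide 8 holds a tumor array of each gel, of mice C and A, whose difference correlated with that of the other arrays at r = 0.631. With slide as a block 2655 passed, and of the 35 called genes named here 22 did. The others were Jsrp1, Bhlha15, Atf5, Dusp6, Cd68, Fn1, Mmp13, Mmp12, Itgb6, Krt18, Krt15, Krt8 and Snai1. The stress response genes had a median of -1.37 with slide as a block and -1.15 within slide 8, the hypoxia and glycolysis genes -1.23 and -1.38. For the FGF and ERK genes these were -0.69 and -0.75, and for the basement membrane components -0.63 and -0.79.

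**Figure D2:**
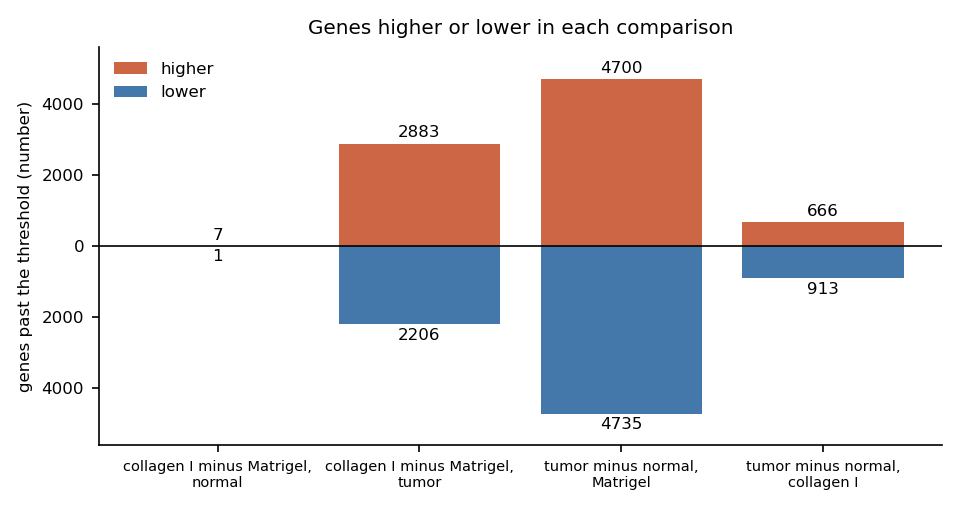
Number of genes that passed the threshold in each comparison, of 18274 tested, with genes higher above and genes lower below the zero line; the tissues in Matrigel differ in most genes, 9435.

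The gel effects of tumor and normal organoids were set against each other. For 245 genes the effect of collagen I was higher in tumor than in normal organoids and for 236 it was lower. The second set held Csf3, which differed by -4.27 ± 0.33, Ddit3 by -3.05 ± 0.37 and Trib3 by -2.62 ± 0.27 (limma adjusted p = 0.000677, 0.00886 and 0.00506). Comp, a matricellular protein of cartilage and fibrosis, differed by -4.99 ± 0.54, and Idi1 by 2.66 ± 0.32 (limma adjusted p = 0.00598 and 0.00816). Those 5 kept their call with any 1 array left out.

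The difference also passed for Pappa at 4.53 ± 0.63, Foxa2, a forkhead factor of endoderm well above background on 1 of 3 normal Matrigel arrays, at -4.40 ± 0.94, Cd68 at -4.07 ± 0.61 and Ccl5 at -3.14 ± 0.57 (limma adjusted p = 0.0136, 0.0414, 0.0183 and 0.0317). It passed for Chac1 at -2.42 ± 0.45, Col18a1 at -1.92 ± 0.39 and Spry2 at -1.51 ± 0.26 (limma adjusted p = 0.0326, 0.0376 and 0.0291). Pappa lost its call without normal collagen I A or B (limma adjusted p = 0.0534 and 0.0503), and Cd68 without any normal collagen I array (0.0534 to 0.0635). Foxa2, Ccl5, Chac1, Col18a1 and Spry2 each lost it without normal Matrigel B or D, any normal collagen I array or tumor collagen I A, and all but Chac1 without tumor Matrigel B (limma adjusted p = 0.0545 to 0.116). Foxa2 lost it also without tumor Matrigel A and tumor collagen I C (0.0514 and 0.0548). Postn, at 3.13 ± 0.78, did not pass (limma adjusted p = 0.0573). None of the 12 genes named in every comparison passed by limma, with adjusted p from 0.115 for Snai1 at -1.46 ± 0.52 to 0.852 for Twist1 at -0.43 ± 1.2. Cdh1 differed by 0.48 ± 0.65, Krt8 by -0.54 ± 0.33, Krt14 by 0.49 ± 1.06, Vim by 0.41 ± 0.77, Snai2 by 1.07 ± 0.43 and Zeb1 by 1.27 ± 0.60. Mmp14 differed by -0.43 ± 0.31, Itga2 by -0.19 ± 0.43, Acta2 by -0.21 ± 0.25 and Trp63 by 0.26 ± 0.45.

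For 5 lists the difference passed as a group. The stress response genes had 6 of 20 members lower, 13 over the list alone, and a median difference of -1.19 (camera adjusted p = 7.85e-10; adjusted p = 0.0947 with an estimated correlation). The FGF and ERK genes had 1 of 20 lower, 6 over the list alone, and a median of -0.81 (camera adjusted p = 0.000902; adjusted p = 0.411 with an estimated correlation). The leukocyte markers had 1 of 15 lower, Cd68, also over the list alone. Their median was -1.37 (camera adjusted p = 0.00142, or 0.635 with an estimated correlation). Some were dim in tumor organoids, so -1.37 may mainly be the normal gel effect. The inflammatory and acute-phase genes had 3 of 25 lower, also over the list alone, and a median of -0.76 (camera adjusted p = 0.0167; adjusted p = 0.396 with an estimated correlation), 0.0775 with normexp and 0.0531 without tumor Matrigel C, at -0.50. Their median was -0.49 without tumor collagen I B and that of the leukocyte markers -0.71 without normal Matrigel B, with the calls kept. The cholesterol biosynthesis genes had 2 of 22 higher, 6 over the list alone, and a median of 0.58 (camera adjusted p = 0.000911; adjusted p = 0.778 with an estimated correlation). With slide as a block these medians were -1.36, -0.83, -1.61, -0.81 and 0.11, and the last lost its call (camera adjusted p = 0.234).

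The count of 481 genes moved with most settings. It was 1712 with the mouse as a random block and 0 with it as a fixed block (limma; 3787 at an unadjusted p under 0.05, and 4772 without the block), where none of the 12 genes named above passed. With slide as a block it was 1349, and Foxa2, Cd68, Chac1 and Spry2 were not among them. Quantile normalization gave 212 genes, the authors' values 142 and normexp with quantile normalization 220, of which 32.7% were higher against 50.9% in the main values. Normexp scaled to the 75th percentile gave 10 genes, 10% of them higher, with a median of all genes at -0.29. Of the 12 genes 10 kept their call with quantile normalization, 9 in the authors' values and 6 with normexp, where Pappa and Foxa2 were at 1.57 and -1.80 (limma adjusted p = 0.301 and 0.209). Leaving out normal Matrigel A gave 2086 genes, B 41 and D 95; normal collagen I A, B and C gave 25, 12 and 36. Without tumor Matrigel A and B it was 809 and 120, and without tumor collagen I A and B 68 and 786.

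Averaged over both tissues, 1701 genes were higher and 985 lower in collagen I. The stress response genes had 10 of 20 lower, 11 over the list alone, with a median of -0.64 (camera adjusted p = 2.96e-07; adjusted p = 0.119 with an estimated correlation). The hypoxia and glycolysis genes had 7 of 19 lower, 10 over the list alone, with a median of -0.77 (camera adjusted p = 5.98e-06; adjusted p = 0.681 with an estimated correlation). The basement membrane components had 3 of 21 lower, 6 over the list alone, with a median of -0.34 (camera adjusted p = 0.0111; adjusted p = 0.635 with an estimated correlation), and missed the threshold with quantile normalization (0.0899) and normexp (0.265). The cell cycle genes had 0 of 28 called by limma, also over the list alone, 1 higher and 5 lower at an unadjusted p under 0.05, and a median of -0.34 (camera adjusted p = 0.0159; adjusted p = 0.837 with an estimated correlation), and 0.242 with normexp. The SRF, YAP and TGF-beta target genes had 5 of 24 higher, also over the list alone, and a median of 0.26 (camera adjusted p = 0.0149; adjusted p = 0.635 with an estimated correlation). The protease genes had 5 of 31 higher, 6 over the list alone, and a median of 0.30 (camera adjusted p = 0.0296; adjusted p = 0.704 with an estimated correlation). The fibroblast markers had 2 of 17 higher and 1 lower, 4 and 1 over the list alone, and a median of 0.65 (camera adjusted p = 0.0388; adjusted p = 0.829 with an estimated correlation). They missed the threshold with the mouse as a random block (camera adjusted p = 0.056), quantile normalization (0.0903), normexp (0.103) and 8 of the 12 arrays left out in turn (0.0518 to 0.111), and were at 1.07 without normal Matrigel D. The protease genes missed it with 6 left out (camera adjusted p = 0.0512 to 0.122; median 0.11 without tumor collagen I C, and 0.47 with the call kept without A), and the cell cycle genes without normal Matrigel A, tumor Matrigel C or tumor collagen I C (0.0625 to 0.144; -0.18 without the last). With slide as a block the medians were -0.69 for the stress response genes, -0.72 for the hypoxia and glycolysis genes and -0.39 for the basement membrane components. The cell cycle genes, at -0.25, the SRF, YAP and TGF-beta target genes, at 0.20, the protease genes, at 0.11, and the fibroblast markers, at 0.65, then had no call (camera adjusted p = 0.278, 0.341, 0.773 and 0.273). The count of 2686 genes was 868 with the mouse and 249 with slide as a fixed block, and 218 with normexp, of which 41.3% were higher against 63.3% in the main values; the median of all genes then lay at -0.18. It was 1789, 1319 and 1150 without normal collagen I A, B and C, 1774 without tumor Matrigel B and 1421 without tumor collagen I A.

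**Figure D3:**
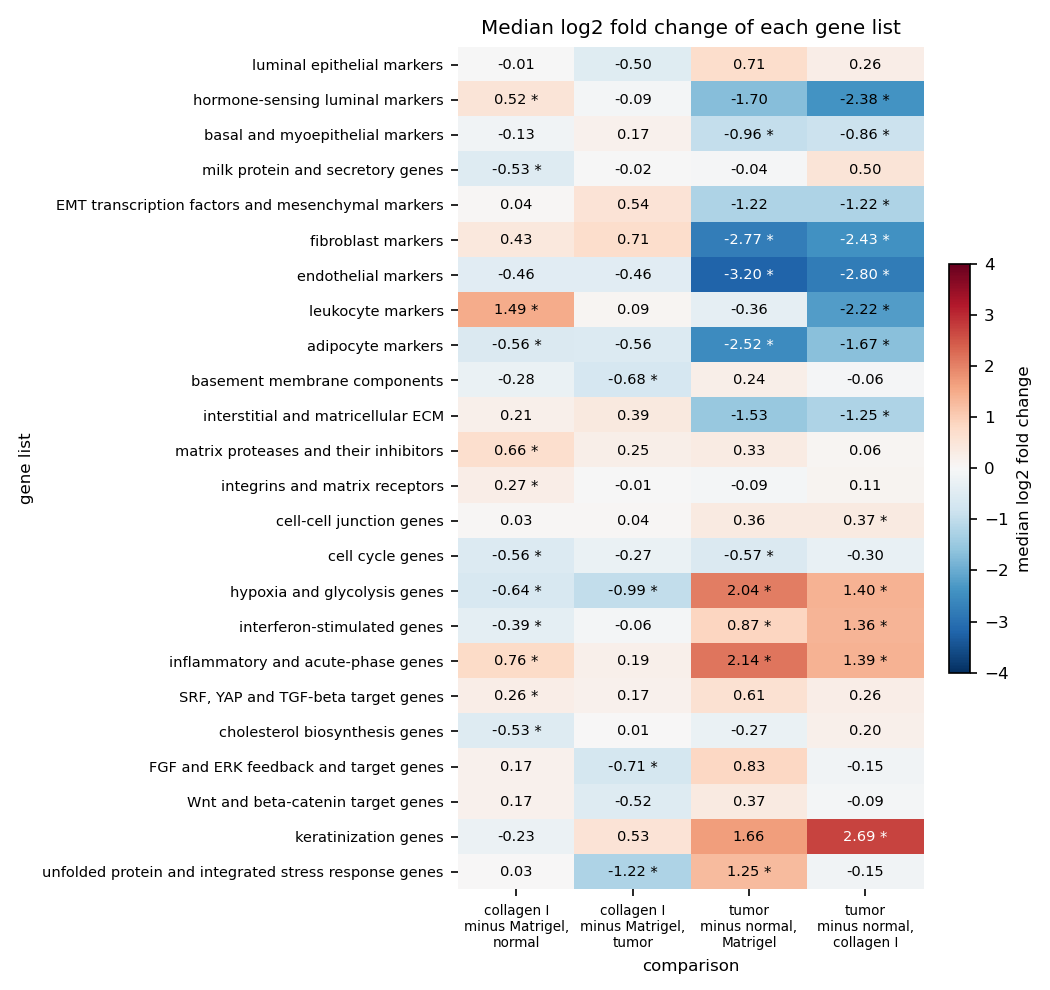
Median log2 fold change of the members of each of the 24 gene lists (rows) in each of the 4 comparisons of 2 groups (columns), as colour and number; a star marks a camera adjusted p under 0.05 with the preset correlation.

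Tumor and normal organoids in Matrigel differed in 9435 genes, 51.6% of those tested, with 4700 higher and 4735 lower in tumor organoids. Crct1, a cornified-cell protein, was 10.22 ± 1.55 higher, Klk6, a kallikrein protease, 7.01 ± 0.68, and Msln, mesothelin, 6.86 ± 0.64 (limma adjusted p = 0.000539, 5.4e-05 and 4.69e-05). Foxa2, at 7.83 ± 0.66, and surfactant protein D (Sftpd), at 5.45 ± 0.53, are genes of lung and endoderm (limma adjusted p = 3.05e-05 and 5.52e-05). Crct1 and Foxa2 were well above background on 1 of 3 normal arrays and Klk6 on 2. With dim arrays at their bound they were 9.40, 7.08 and 7.00 higher, and with normexp 6.99, 4.67 and 5.06. Degs2, S100a9, an alarmin of myeloid and inflamed epithelial cells, and Orm1, an acute-phase glycoprotein, were not well above background in normal organoids and were at least 150-fold, 99.2-fold and 30.4-fold higher in tumor organoids (limma adjusted p = 0.000259, 0.00853 and 1.12e-06). Without tumor Matrigel C the bound of S100a9 was 33.2-fold and without B 203-fold, and it lost its call with normexp and quantile normalization (limma adjusted p = 0.0555). Smooth muscle myosin (Myh11) was lower at -7.05 ± 0.46, the secreted scavenger receptor Dmbt1 at -7.60 ± 0.57 and the growth factor pleiotrophin (Ptn) at -7.00 ± 0.73 (limma adjusted p = 7.58e-06, 1.5e-05 and 8.42e-05). Col14a1, a fibril-associated collagen, and the stem cell receptor Lgr5 were not well above background in tumor organoids and at least 103-fold and 44.9-fold lower there (limma adjusted p = 7.17e-09 and 0.000232).

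Of the luminal epithelial markers 9 of 16 were higher and 2 lower, also over the list alone, with a median of 0.71 (camera adjusted p = 0.0706). The tight junction gene Cldn4 rose by 2.99 ± 0.54, Krt7 by 2.60 ± 0.40 and Elf3 by 1.42 ± 0.21 (limma adjusted p = 0.00135, 0.000553 and 0.000465). Of the hormone-sensing luminal markers 2 of 11 were higher and 6 lower, also over the list alone, with a median of -1.70, or -1.35 with dim genes at their bound (camera adjusted p = 0.0898). Tbx3, a T-box factor, was at -4.73 ± 0.40 and the pioneer factor Foxa1 at -3.35 ± 0.75 (limma adjusted p = 2.94e-05 and 0.00402). The estrogen-induced gene Greb1 was at least 7.63-fold and the progesterone receptor (Pgr) at least 2.56-fold lower (limma adjusted p = 1.9e-05 and 8.8e-05). Pgr turned to 0.77 higher with normexp. Of the basal and myoepithelial markers 2 of 16 were higher and 8 lower, also over the list alone, with a median of -0.96 (camera adjusted p = 0.0279; adjusted p = 0.438 with an estimated correlation). The contractile genes Cnn1, at -5.48 ± 0.29, and Mylk, at -4.13 ± 0.37, fell (limma adjusted p = 2.02e-06 and 3.65e-05). The milk protein and secretory genes went both ways, 6 of 15 higher and 4 lower, also over the list alone, with a median of -0.04 (camera adjusted p = 0.833): lactoferrin (Ltf) was at 4.79 ± 0.76 and alpha-lactalbumin (Lalba) at -3.47 ± 0.84 (limma adjusted p = 0.000689 and 0.00625).

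Of the endothelial markers 11 of 13 were lower and 0 higher, also over the list alone, with a median of -3.20 (camera adjusted p = 2.83e-06; adjusted p = 0.396 with an estimated correlation). They include the endothelial junction genes Cldn5 at -5.85 ± 0.50, Cdh5 at -5.10 ± 0.62 and Pecam1 at -4.77 ± 0.58 and the receptor Tie1, at least 16.5-fold lower (limma adjusted p = 3.09e-05, 0.000188, 0.000186 and 1.22e-05). Of the fibroblast markers 1 of 17 was higher and 15 lower, also over the list alone, with a median of -2.77, or -2.65 with dim genes at their bound (camera adjusted p = 0.000112; adjusted p = 0.678 with an estimated correlation). The fibrillar collagen Col3a1 was at -5.16 ± 0.72, Postn at -4.38 ± 0.55 and Col6a1 at -3.79 ± 0.51 (limma adjusted p = 0.000379, 0.000214 and 0.000291). Of the adipocyte markers 3 of 6 were lower, 4 over the list alone, with a median of -2.52 (camera adjusted p = 0.0459; adjusted p = 0.725 with an estimated correlation), and the lipid carrier Fabp4 was at -4.70 ± 0.46 (limma adjusted p = 5.55e-05). The leukocyte markers had 1 of 15 higher and 2 lower, 1 and 0 over the list alone, and a median of -0.36, or 0 with dim genes at their bound (camera adjusted p = 0.781). Cd68 was at 4.16 ± 0.43 (limma adjusted p = 7.91e-05) and Lyz2 at -2.37 ± 0.82, with overlapping arrays (limma adjusted p = 0.032). The EMT genes had 2 of 14 higher and 7 lower, also over the list alone, with a median of -1.22 (camera adjusted p = 0.0655). Zeb1 was at -4.03 ± 0.42, S100a4 at -2.45 ± 0.63 and Vim at -2.04 ± 0.55, Zeb2 was at least 6.91-fold lower, and Snai1 was higher at 1.26 ± 0.37 (limma adjusted p = 8.36e-05, 0.00846, 0.0101, 0.000217 and 0.0149).

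Of the interstitial and matricellular ECM genes 5 of 25 were higher and 15 lower, 6 and 15 over the list alone, with a median of -1.53 (camera adjusted p = 0.0655). Of the basement membrane components 6 of 21 were higher and 5 lower, also over the list alone, with a median of 0.24 and a mean of -0.21 (camera adjusted p = 0.545): Nid2 was at -4.60 ± 0.65, Lama1 at -4.26 ± 0.46 and Col18a1 at 2.30 ± 0.28 (limma adjusted p = 0.000383, 9.46e-05 and 0.000181). The protease genes had 10 of 31 higher and 5 lower, 9 and 4 over the list alone, and a median of 0.33 (camera adjusted p = 0.544). Mmp7 was at 3.44 ± 0.78 and Mmp13 at 2.98 ± 0.70 (limma adjusted p = 0.00444 and 0.00524). The integrins and matrix receptors had 8 of 23 higher and 7 lower, also over the list alone, and a median of -0.09, or 0 with dim genes at their bound (camera adjusted p = 0.919). Itga3 was at 3.19 ± 0.29, the proteoglycan Sdc1 at 2.4 ± 0.44 and Itga9 at -2.95 ± 0.53 (limma adjusted p = 3.97e-05, 0.00139 and 0.00135). The cell-cell junction genes had 11 of 27 higher and 3 lower, also over the list alone, and a median of 0.36 (camera adjusted p = 0.148).

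Stress, hypoxia and inflammation genes were higher in tumor organoids. These shifts rest on the dim tumor Matrigel arrays, which the gel effect in tumor organoids also uses. The stress response genes had 16 of 20 higher and 0 lower, 17 and 1 at an unadjusted p under 0.05, and 16 higher over the list alone, with a median of 1.25 (camera adjusted p = 1.44e-05; adjusted p = 0.187 with an estimated correlation). Ddit3 was at 3.89 ± 0.26, Trib3 at 2.37 ± 0.19 and Chac1 at 2.24 ± 0.31 (limma adjusted p = 8.15e-06, 1.94e-05 and 0.000378). The hypoxia and glycolysis genes had 15 of 19 higher, 16 over the list alone, and a median of 2.04 (camera adjusted p = 5.45e-05; adjusted p = 0.725 with an estimated correlation). Adm was at 5.37 ± 0.67, the carbonic anhydrase Car9 at 3.01 ± 0.60 and Ndrg1 at 2.98 ± 0.54 (limma adjusted p = 0.000204, 0.00231 and 0.00139). The inflammatory and acute-phase genes had 19 of 25 higher and 2 lower, 19 and 3 over the list alone, with a median of 2.14, or 2.04 with dim genes at their bound (camera adjusted p = 0.000151; adjusted p = 0.152 with an estimated correlation). Csf3 was at 5.14 ± 0.23 and Ccl5 at 4.71 ± 0.40, and the lung chemokine Cxcl15 was at least 17.1-fold lower (limma adjusted p = 1.01e-06, 3.14e-05 and 9.45e-05). The interferon-stimulated genes had 13 of 23 higher and 1 lower, 14 and 1 over the list alone, and a median of 0.87 (camera adjusted p = 0.0239; adjusted p = 0.837 with an estimated correlation). Oasl1 was at 2.90 ± 0.43, Irf7 at 2.47 ± 0.43 and Bst2 at 2.21 ± 0.34 (limma adjusted p = 0.000477, 0.00116 and 0.000601). They lost the call with quantile normalization (camera adjusted p = 0.0574), normexp (0.265) and the mouse as a random block (0.0602). The AP-1 factor Fosl1 was at 3.64 ± 0.51 (limma adjusted p = 0.000369), and the FGF and ERK genes had 11 of 20 higher and 2 lower, also over the list alone, and a median of 0.83 (camera adjusted p = 0.0655). The cell cycle genes had 9 of 28 lower, 8 over the list alone, and a median of -0.57 (camera adjusted p = 0.0212; adjusted p = 0.837 with an estimated correlation), and 0.07 with the mouse as a random block. The mitotic genes Kif11, Bub1 and Mki67 were at -2.64 ± 0.40, -2.13 ± 0.40 and -1.91 ± 0.40 (limma adjusted p = 0.000542, 0.00171 and 0.00305). The cholesterol biosynthesis genes had 7 of 22 lower, also over the list alone, and a median of -0.27 (camera adjusted p = 0.118). Idi1 was at -2.76 ± 0.22 and the sterol carrier Stard4 at -1.57 ± 0.26 (limma adjusted p = 2.33e-05 and 0.000813).

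Of the other genes named in every comparison, Krt8 was at 0.82 ± 0.23 and Trp63 at 0.94 ± 0.32 (limma adjusted p = 0.0127 and 0.028). Krt8 turned without a call under the same 3 settings as between the gels in tumor organoids, and had an adjusted p of 0.0515 without normal Matrigel D. Trp63 lost its call under each of the 5 other scalings, with slide as a block (limma adjusted p = 0.18) and without normal Matrigel B or D or tumor Matrigel A or C (0.0528 to 0.107). Cdh1 was at -0.20 ± 0.46, Krt14 at 1.08 ± 0.75, Snai2 at -0.22 ± 0.30, Twist1 at 0.66 ± 0.85, Mmp14 at -0.37 ± 0.22, Itga2 at 0.30 ± 0.30 and Acta2 at -0.04 ± 0.17, all without a call (limma adjusted p = 0.184 to 0.863). Snai1 missed the threshold without tumor Matrigel B (limma adjusted p = 0.0525), and Lyz2 without normal Matrigel A or D or tumor Matrigel A or C (0.073 to 0.128).

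Of the 9435 genes 1204 were dim on 1 side. The fit with normexp called 9160 genes, 77.1% of them higher against 49.8% in the main values, with the median of all genes at 0.45; 5951 were called by both, 5375 of them in the same direction. Greb1, Foxa1, Zeb1, Zeb2, Tie1, Kif11, Krt8 and Trp63 then had no call. Slide 4 holds a normal and a tumor Matrigel array, of mice D and B, whose difference correlated with that of the other arrays at r = 0.856. With slide as a block Lalba, S100a4, Lyz2, Mmp7, Vim and Trp63 had no call. The list medians with slide as a block and within slide 4 were -3.27 and -3.75 for the endothelial markers, -3.23 and -4.05 for the fibroblast markers, -0.44 and -0.25 for the basal and myoepithelial markers and 1.22 and 1.25 for the stress response genes. They were 2.67 and 2.85 for the hypoxia and glycolysis genes and 2.45 and 2.39 for the inflammatory and acute-phase genes. The adipocyte markers, at -3.88 and -4.92, the cell cycle genes, at -0.56 and 0.05, and the interferon-stimulated genes, at 0.96 and 0.94, lost their call with the block (camera adjusted p = 0.293, 0.14 and 0.218). The adipocyte markers also lost it with quantile normalization (camera adjusted p = 0.0666) and without normal Matrigel D, at -1.19, or tumor Matrigel A or C (0.0678 to 0.0914). Without normal Matrigel A the basal and myoepithelial markers, at -0.75, and the cell cycle genes, at -0.31, lost it (camera adjusted p = 0.097 and 0.194). Without tumor Matrigel A the first had an adjusted p of 0.05, and without C the interferon-stimulated genes one of 0.0866. On the dimmer side Cdh5, Pecam1, Nid2 and Lama1 were well above background on 2 of 3 arrays, at -4.77, -4.29, -4.13 and -3.98 with dim arrays at their bound, and Zeb1 and Mmp7 on 1, at -3.86 and 2.81.

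In collagen I fewer genes separated the tissues: 666 were higher and 913 lower in tumor organoids, 8.64% of those tested. The kallikreins Klk6 and Klk14 were 6.05 ± 0.68 and 5.04 ± 0.87 higher, Msln 4.45 ± 0.64 and Krt16, a keratin of stressed epidermis, 5.53 ± 1.09 (limma adjusted p = 0.000285, 0.00465, 0.00158 and 0.0103). The serotonin transporter Slc6a4 was not well above background in normal organoids and at least 38.7-fold higher (limma adjusted p = 1.59e-05). Dmbt1, at -7.68 ± 0.57, and Ptn, at -7.56 ± 0.73, were among the lowest (limma adjusted p = 3.34e-05 and 0.000115). Col14a1 and the embryonic tight junction gene Cldn6 were not well above background in tumor organoids and at least 81.4-fold and 28.8-fold lower (limma adjusted p = 1.66e-08 and 0.000464).

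Of the endothelial markers 11 of 13 were lower, 12 over the list alone, with a median of -2.80 (camera adjusted p = 1.43e-17; adjusted p = 0.0947 with an estimated correlation). Cldn5 was at -6.37 ± 0.50, Cdh5 at -6.32 ± 0.62, Emcn, endomucin, at -6.14 ± 0.62 and Tie1 at least 15.3-fold lower (limma adjusted p = 3.57e-05, 0.000122, 0.00014 and 2.11e-05). Of the fibroblast markers 12 of 17 were lower and 0 higher, 14 and 1 over the list alone, with a median of -2.43 (camera adjusted p = 3.88e-09; adjusted p = 0.411 with an estimated correlation). Col3a1 was at -4.14 ± 0.72, Col6a1 at -3.09 ± 0.51 and the pericyte receptor Pdgfrb at -3.18 ± 0.52 (limma adjusted p = 0.00506, 0.00337 and 0.00331). Of the leukocyte markers 8 of 15 were lower, 10 over the list alone, with a median of -2.22, or -1.77 with dim genes at their bound (camera adjusted p = 4.11e-05; adjusted p = 0.532 with an estimated correlation). The pan-leukocyte phosphatase Ptprc was at -3.59 ± 0.79 and the myeloid adaptor Tyrobp at -3.54 ± 0.75 (limma adjusted p = 0.0181 and 0.0147). The adipocyte markers had 2 of 6 lower, also over the list alone, and a median of -1.67 (camera adjusted p = 0.00556; adjusted p = 0.635 with an estimated correlation). Fabp4 was at -4.03 ± 0.46 (limma adjusted p = 0.000326). The EMT genes had 5 of 14 lower, 8 lower and 1 higher over the list alone, and a median of -1.22 (camera adjusted p = 0.000176; adjusted p = 0.211 with an estimated correlation). Zeb1 was at -2.76 ± 0.42 and Zeb2 at -3.36 ± 0.54 (limma adjusted p = 0.00216 and 0.00305).

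The hormone-sensing luminal markers had 1 of 11 higher and 7 lower, 1 and 8 over the list alone, and a median of -2.38 (camera adjusted p = 1.79e-05; adjusted p = 0.187 with an estimated correlation). Tbx3 was at -5.15 ± 0.40 and Foxa1 at -4.20 ± 0.75, and Greb1 and Pgr were at least 8.18-fold and 5.64-fold lower (limma adjusted p = 3.57e-05, 0.00577, 7.67e-05 and 7.89e-05). The basal and myoepithelial markers had 1 of 16 higher and 6 lower, 3 and 9 over the list alone, and a median of -0.86 (camera adjusted p = 0.00168; adjusted p = 0.238 with an estimated correlation). The contractile genes Myh11, Cnn1 and Mylk were at -5.79 ± 0.46, -4.84 ± 0.29 and -4.05 ± 0.37 (limma adjusted p = 3.57e-05, 1.44e-05 and 6.94e-05). The luminal epithelial markers had 0 of 16 called by limma, also over the list alone, 3 higher at an unadjusted p under 0.05, and a median of 0.26 (camera adjusted p = 0.275). The cell-cell junction genes had 1 of 27 higher, Cldn1 at 1.69 ± 0.28 (limma adjusted p = 0.00403), 3 higher and 1 lower over the list alone, and a median of 0.37 (camera adjusted p = 0.0279; adjusted p = 0.678 with an estimated correlation). The keratinization genes had 4 of 18 higher and 2 lower, 10 and 2 over the list alone, and a median of 2.69, or 2.36 with dim genes at their bound (camera adjusted p = 0.0111; adjusted p = 0.778 with an estimated correlation). The milk protein and secretory genes had 2 of 15 higher, also over the list alone, and a median of 0.50 (camera adjusted p = 0.365). Ltf was at 3.96 ± 0.76 (limma adjusted p = 0.00884).

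The hypoxia and glycolysis genes had 10 of 19 higher, 18 over the list alone, and a median of 1.40 (camera adjusted p = 4.67e-09; adjusted p = 0.635 with an estimated correlation). Adm was at 3.45 ± 0.67 and the angiogenic factor Vegfa at 2.38 ± 0.43 (limma adjusted p = 0.00922 and 0.00651). The interferon-stimulated genes had 12 of 23 higher, 16 over the list alone, and a median of 1.36 (camera adjusted p = 9.6e-08; adjusted p = 0.635 with an estimated correlation). Oas2 was at 3.90 ± 0.64, Oasl1 at 2.56 ± 0.43 and Irf7 at 2.33 ± 0.43 (limma adjusted p = 0.00326, 0.00389 and 0.00732). The inflammatory and acute-phase genes had 12 of 25 higher and 3 lower, 17 and 4 over the list alone, and a median of 1.39 (camera adjusted p = 2.15e-05; adjusted p = 0.119 with an estimated correlation). Serum amyloid A1 (Saa1) was at 3.83 ± 0.76, the cytokine Il1a at least 7.36-fold higher (4.08-fold without tumor collagen I C) and Cxcl15 at -5.74 ± 0.66 (limma adjusted p = 0.0103, 0.00286 and 0.000329). The interstitial and matricellular ECM genes had 1 of 25 higher and 11 lower, 4 and 12 over the list alone, and a median of -1.25 (camera adjusted p = 0.000808; adjusted p = 0.635 with an estimated correlation). Nid2, at -4.59 ± 0.65, Lama1, at -3.07 ± 0.46, the metalloprotease Mmp23, at -2.24 ± 0.22, and the integrin Itga8, at -2.14 ± 0.31, were lower from lists without a camera call (limma adjusted p = 0.00133, 0.00195, 0.000118 and 0.00149). So were Lgr5 at -5.74 ± 0.84 and the ligand Wnt5a at -1.90 ± 0.34 of the Wnt and beta-catenin target genes, with 1 of 20 higher and 3 lower, 2 and 4 over the list alone, and a median of -0.09 (camera adjusted p = 0.203; limma adjusted p = 0.00172 and 0.00571). The immediate-early factor Egr2 was at -2.07 ± 0.39 (limma adjusted p = 0.00803). The stress response genes had 1 of 20 higher and 1 lower, also over the list alone, and a median of -0.15 with a mean of 0.09 (camera adjusted p = 0.958).

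Mmp14, at -0.81 ± 0.22, and Trp63, at 1.2 ± 0.32, passed narrowly (limma adjusted p = 0.0487 and 0.0395). Mmp14 lost its call with the mouse as a random block (limma adjusted p = 0.0537), with normexp (0.152) and without any 1 array other than normal Matrigel A and tumor Matrigel A and C (0.0549 to 0.184). Trp63 lost it with quantile normalization (limma adjusted p = 0.0559), normexp (0.0795), the authors' values (0.0597) and without normal Matrigel B, tumor Matrigel A, any normal collagen I array or tumor collagen I B or C (0.056 to 0.132). Ptprc lost it without normal collagen I B or C or tumor collagen I B (0.0625 to 0.0796), and Tyrobp without normal collagen I C or tumor collagen I B (0.0671 and 0.0534). Cdh1 was at 0.28 ± 0.46, Krt8 at 0.28 ± 0.23, Krt14 at 1.57 ± 0.75, Vim at -1.64 ± 0.55, Snai1 at -0.20 ± 0.37, Snai2 at 0.85 ± 0.30, Twist1 at 0.22 ± 0.85, Itga2 at 0.11 ± 0.30 and Acta2 at -0.25 ± 0.17, all without a call (limma adjusted p = 0.0969 to 0.907). Vim passed with quantile normalization (limma adjusted p = 0.0387).

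Normexp gave 743 genes in place of 1579, 56.5% of them higher against 42.2% in the main values, with the median of all genes at 0.16. It ended the calls of Tie1, Greb1, Pgr, Zeb1, Zeb2, Ptprc, Lama1, Mmp23, Wnt5a, Mmp14 and Trp63. Without normal collagen I A, B or C the count was 1040, 822 or 754, and without tumor collagen I B 931. Slide 6 holds a normal array of mouse B and a tumor array of mouse C, whose difference correlated with that of the other arrays at r = 0.737; with slide as a block 192 genes passed, and 18 of the 47 called genes named here. The list medians with that block and within slide 6 were -3.44 and -3.56 for the endothelial markers, -2.07 and -2.28 for the fibroblast markers, -2.12 and -2.4 for the hormone-sensing luminal markers, -0.87 and -1.2 for the basal and myoepithelial markers and -1.23 and -1.18 for the EMT genes. They were 1.56 and 1.61 for the hypoxia and glycolysis genes, 1.46 and 1.5 for the interferon-stimulated genes, 1.54 and 1.46 for the inflammatory and acute-phase genes and 3.37 and 5.23 for the keratinization genes. The leukocyte markers, at -2.53 and -1.97, the adipocyte markers, at -1.71 and -2.36, the interstitial and matricellular ECM genes, at -0.75 and -1.10, and the cell-cell junction genes, at 0.37 and 0.43, lost their call with the block (camera adjusted p = 0.0618, 0.168, 0.324 and 0.385). The cell-cell junction genes also lost it with quantile normalization and normexp (0.115 and 0.237) and without normal collagen I C or tumor collagen I C (0.0637 and 0.131), and the keratinization genes, at 1.66, without tumor collagen I C (0.125). On the dimmer side Klk14, Cldn5, Emcn, Foxa1, Lama1 and Wnt5a were well above background on 2 of 3 arrays, and Cdh5, Ptprc, Nid2, Cxcl15 and Lgr5 on 1. With dim arrays at their bound the last 5 were at -5.65, -2.55, -3.84, -4.99 and -4.89; with normexp Ptprc was at -0.50.

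**Figure D4:**
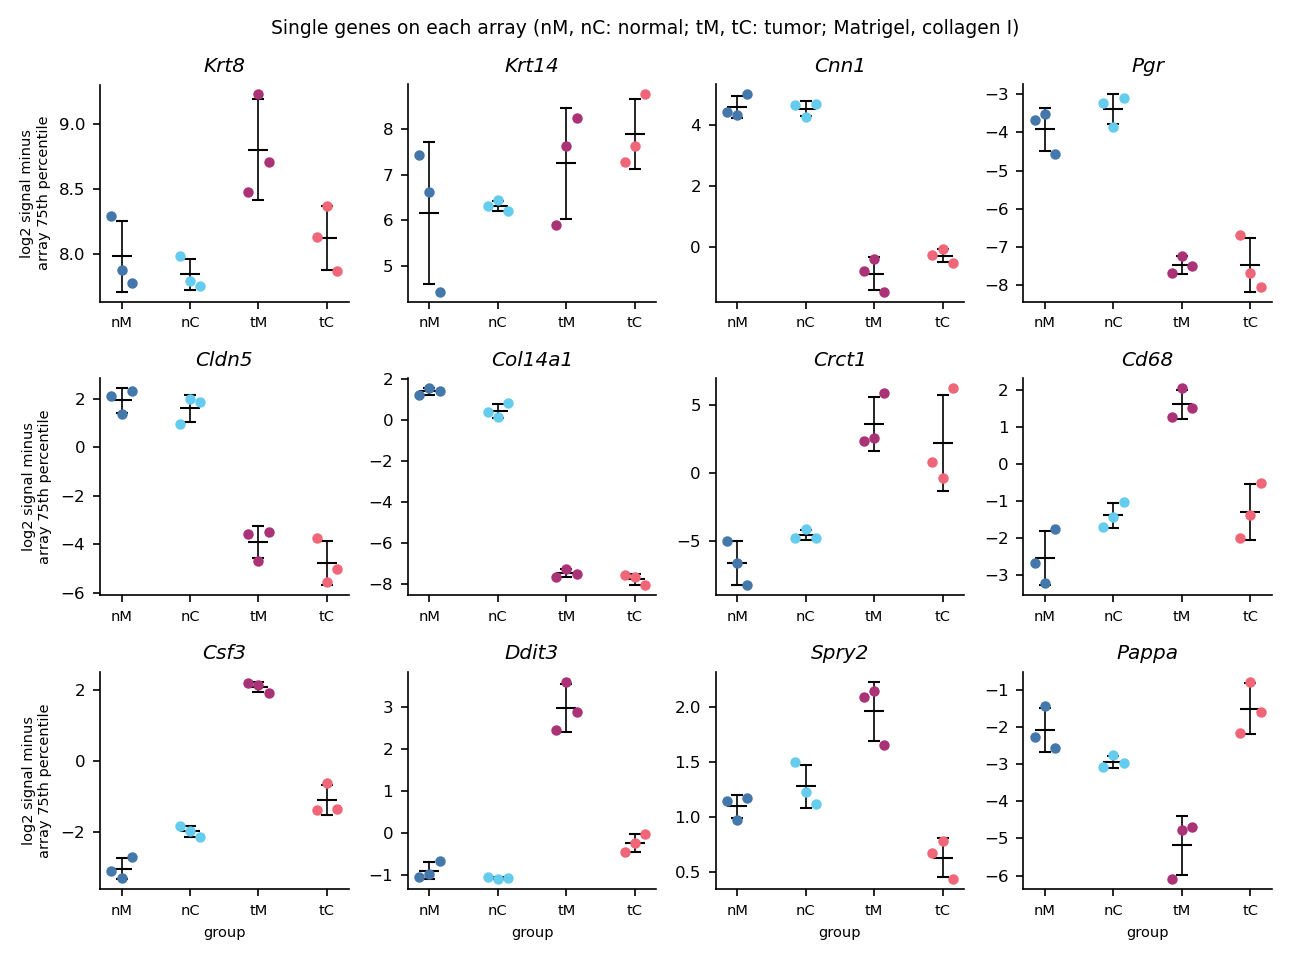
Log2 signal minus the array's 75th percentile of 12 genes on the 12 arrays, by group; points are arrays and bars the mean and SD (n = 3), with Csf3 and Ddit3 highest in tumor organoids in Matrigel and Cnn1, Cldn5 and Col14a1 low in tumor organoids in both gels.

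The effects were set side by side for pairs of comparisons that share no arrays. Across 18274 genes, which are not independent replicates, the gel effects in normal and tumor organoids correlated at r = 0.307 (rho = 0.228), and 56.5% of genes had the same sign. Of the 5089 genes that passed in tumor organoids, 63.2% had the same sign in normal organoids. Both lists held 4 genes higher in collagen I, where independent lists give 1.1, and 0 lower. The differences between tumor and normal organoids in Matrigel and in collagen I correlated at r = 0.747 (rho = 0.725), with 78.1% of genes of the same sign. Both gels held 579 genes higher and 773 lower in tumor organoids. Tumor mice A, B and C and normal mice A and B are in both, so part of this and of the correlation may come from shared mice. Of the genes 13 passed in opposite directions, and 97.0% of the genes that passed in collagen I had the same sign in Matrigel. Without normal Matrigel A the correlation of the gel effects was 0.07.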

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

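The tests of other scalings, of the leukocyte markers, of the chaperones, of normal Matrigel A and of the splits that part each mouse were chosen only after the result was seen. The tested difference of the gel effects between tissues passed for 481 genes. Its list medians were -1.37 for the leukocyte markers, -0.76 for the inflammatory and acute-phase genes and 0.58 for the cholesterol biosynthesis genes. They were -0.81 for the FGF and ERK genes and -1.19 for the stress response genes. Single genes differed by 4.53 (Pappa), 2.66 (Idi1), -4.99 (Comp), -4.40 (Foxa2), -4.27 (Csf3), -4.07 (Cd68), -3.14 (Ccl5), -3.05 (Ddit3), -2.62 (Trib3), -2.42 (Chac1), -1.92 (Col18a1) and -1.51 (Spry2); with normexp Pappa was at 1.57 and Foxa2 at -1.80, without a call. For Comp the gel effect was 2.05 in normal and -2.94 in tumor organoids, and for Idi1 -1.19 and 1.47. Spike-in RNA, which the comparisons do not use, stood 2.55 log2 units over the 75th percentile on the tumor Matrigel arrays. Of 100 drawn splits of the arrays, 3 gave as many genes as the difference (real split included); the 2 others, with 2686 as the highest, exchange the tumor gels and so carry their gel effect. So do the 4 others of the 5 that gave as many among the 32 splits that part the gels of each mouse; the rest gave 197 at most. Neither count decides on chance, which stays open for the difference; with the mouse as a fixed block 0 genes passed (limma; 3787 at an unadjusted p under 0.05). For the average 2 of 100 gave 2686 or more (highest other 3188) and 1 of those 32 (highest other 1746). Both others keep the tumor gels, so chance stays open.

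More genes passed between the gels in tumor than in normal organoids, 5089 against 8. Among the 4569 brightest genes the SD of the fold changes was 1.92 times as large in tumor organoids (1.7 to 2.14 with an array left out). Loss of dim genes as the whole cause called for a ratio near 1. The lowest ratio of the counts under another scaling was 45.4. The ratios argue against the choice among these scalings and against that loss as the whole cause. Each of these scalings sets the arrays to a common level and none uses the spike-in RNA, so a fault they share stays open. Other faults of dim arrays stay open. Only the real split gave as many genes (highest others 4 and 8 in normal and tumor organoids). In each, 10 splits are too few for a share under 0.05. Without normal Matrigel A the normal count was 15, and without 1 tumor Matrigel array the tumor count was at least 2895, 193 times as many, which argues against the spread of that array as the whole cause. As part of it that spread stays open, since array weights raised the normal count to 1686. A different response of the tissues may remain.

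Stromal and vascular markers were lower in tumor organoids in both gels. None of 10000 random lists matched on signal (0%) had a median as low as the endothelial markers in Matrigel (-3.20; lowest list -2.06), which argues against dim arrays. A smaller share of all non-epithelial cells would lower leukocyte markers alike. In Matrigel the 15 leukocyte markers were at -0.36 against -2.99 for the other markers (permutation p = 3e-04, over genes, which are not independent replicates), but only 2 of the 15 were bright enough in normal organoids to show such a fall. In collagen I they were at -2.22 against -2.62 (permutation p = 0.463), with 9 of 15 bright enough. A smaller share stays open in both gels. Only the real one of 10 splits gave as many genes in either gel (9435 and 1579, highest other 0 by limma in both). For a share under 0.05, 10 are too few.

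The stress response genes were lower in tumor organoids in collagen I than in Matrigel. None of 10000 matched lists had a median as low as -1.22 (lowest -0.78), which argues only against dim arrays lowering all such genes. Without each tumor array in turn the median stayed at -0.94 or lower, which argues against 1 culture as the whole cause. The 8 chaperones and folding enzymes, from Herpud1 at -1.34 to Hsp90b1 at -0.08, had a median of -0.66 and the 12 other members, from Ddit3 at -3.23 to Sesn2 at -0.65, one of -1.41 (exact permutation p = 0.00305 over genes, which are not independent replicates). Unfolded proteins need not lower both sets alike, so they stay open as a cause. Of the 8, 5 were lower by limma. A response to amino acid or other stress in Matrigel may remain as a hypothesis, untested here.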

How the results depend on the processing

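The tests with normexp scaled to the array median were chosen after seeing the data. The causes of the changes below were not tested. By construction the 2-fold threshold, the stricter filter, the fixed blocks and fits of fewer arrays or groups have fewer genes or arrays. The gel effect in normal organoids (8 genes) gave 18 with quantile normalization, 4 with normexp, 88 with normexp and quantile normalization and 4 with normexp and the array median. It gave 13 with both batches averaged, 51 with 14 arrays, 69 with batch 1 in place of batch 2, 51 with slide as a random and 0 with it as a fixed block (limma; 1874 at an unadjusted p under 0.05). It gave 3 from the groups compared alone, 16 with trend and robust variances and 1686 with array weights (which take genes in turn, here by name). With the mouse as a replicate block, which pairs the gels, it gave 71 (random) and 0 (fixed; 1659 at an unadjusted p under 0.05), the difference of effects 1712 and 0 (3787) and the averaged effect 868 (fixed). The block changed no other count by over 1.5 times. The gel effect in tumor organoids (5089) gave 1251 with normexp, 1159 with the array median, 2655 with slide as a fixed block, 2264 from the groups compared alone and 2829 at 2-fold. Tumor against normal gave 6045 at 2-fold in Matrigel (9435), and in collagen I (1579) 743 with normexp, 818 with the array median, 952 with probes above background on every array and 192 with slide as a fixed block. The difference of effects (481) gave 212, 10, 220 and 15 under the scalings in the order above, 142 in the authors' values, 59 without a filter, 2222, 1291 and 3032 with the uses of batch 1, 1672 and 1349 with slide as a random and fixed block, 1001 with trend and robust variances and 3440 with array weights. The averaged effect (2686) gave 218 with normexp, 233 with the array median, 1577 without a filter, 249 with slide as a fixed block and 1185 at 2-fold. Leaving out each array gave 4 to 23 genes for the gel effect in normal and 2744 to 5413 in tumor organoids, 7402 to 9725 in Matrigel, 754 to 1873 in collagen I, 12 to 2086 for the difference and 1150 to 3224 for the average. The correlation of the gel effects was 0.0668 to 0.395 with an array left out and 0.00554 with batch 1 in place of batch 2. With an estimated correlation 0 list tests passed by camera (17 at an unadjusted p under 0.05), and fry called 37, of which 29 were among the 50. Leaving out each array gave 45 to 63, tests chosen after the results were seen. Krt8 turned to 0.09, 0.145 and 0.058 between the gels in tumor organoids and to -0.165, -0.164 and -0.03 between the tissues in Matrigel, with quantile normalization, normexp and quantile normalization, and the authors' values. Pgr turned to 0.769 and 0.77 in Matrigel with normexp and either scaling, and Acta2 to 1.459 between the gels in tumor organoids with the mean of its probes. Of the 338 called pairs of a gene and a comparison under the naming rule, 302 were called in the same direction with quantile normalization, 216 with normexp, 291 with normexp and quantile normalization, 220 with the array median and 296 in the authors' values; 2, 16, 2, 15 and 2 had the opposite direction. The dim tumor Matrigel arrays limit what can be measured there.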

Other observations

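No test in this part was chosen before the result was seen, and none offers a cause. Normal Matrigel mice A and B were hybridised in both batches, and the repeats of a sample correlated at 0.967 and 0.986 across genes, which are not independent replicates. The difference of mouse A from mouse B in batch 2 correlated with that in batch 1 at r = 0.108 (rho = 0.0296) and had an SD of 0.693 against 0.376. The cell cycle genes had a median difference between A and B of 0.28 in batch 2 and -0.33 in batch 1, and the leukocyte markers 1.64 and 0.87.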
